A study of Homo sapiens with 60 samples.

How the data were processed

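RNA was measured in 60 human biopsy samples that the labels place in 1 group, with skin as the tissue and a single core biopsy from each patient. The labels say that tissue was either formalin-fixed and paraffin-embedded or fresh frozen, without saying which sample was which. Total RNA was made into strand-preserving libraries and sequenced as paired-end reads of 100 bp, per the labels' protocols.

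The deposited matrix holds estimated counts per gene for 58676 Ensembl gene identifiers in 60 columns, and each column name equalled the title of a single sample. Kallisto, which estimates counts by pseudoalignment to transcripts, limma and edgeR are named in the submitters' processing notes. Their versions, the transcript set, the genome build and the strand setting of the counting are not given in the sources used here. Estimated counts need not be whole numbers. Among the 36144 genes with 1 annotated transcript, only 0.684% of the non-zero values lay within 0.001 of a whole number, so the deposited values may have been rescaled before deposition, and they were rounded to whole numbers here. Symbols, gene types and coordinates were taken from GENCODE release 29, which named all 58676 identifiers. Its build may differ from the one behind the counts.

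The labels name no inflamed and non-inflamed samples. No groups were formed from measured values, and a T-cell score was used as a continuous measure. The score was the mean log2 CPM (counts per 1e6, with a prior count of 2 and TMM scaling) of 15 T-cell genes, among them CD2, CD3E, CD5 and CD8A, all of which were measured. The library names begin with either YZ (22 libraries) or YZHA (38 libraries). The meaning of these beginnings is not given, and they were treated as a possible batch, called the name series below. Whether a name series also marks a way of preserving tissue is not known from the labels.

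The low-count filter of edgeR (filterByExpr with its minimum count of 10 and the name series as design) left 26428 genes. The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3) on the rounded counts with TMM scaling and Benjamini-Hochberg adjustment over all genes tested, at a threshold of 0.05. For the T-cell score, the model held the score and the name series, and a slope is the log2 change per log2 unit of score. The 15 score genes were left out of every count of associated genes, because their association follows from how the score is made. For the name series, the model held the series alone. For slopes that differed between name series, the model added their interaction with the score, centred within each series. The standard error (SE) of a slope or log2 difference was its size divided by the square root of the F statistic.

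Gene lists were tested with camera in limma 3.58.1 on voom values, with a preset correlation of 0.01 between genes and again with an estimated correlation, and adjusted over 52 lists for the score and 53 for the name series. List scores were correlated with the T-cell score by Pearson's r and Spearman's rho, with two-sided permutation tests of 100000 resamples in scipy 1.17.1 and numpy 2.4.6. The smallest p these can give is 1e-05. Genes of the T-cell list were removed from every other list. Some of the other lists share genes with each other, so counts of passing lists are not counts of independent results. A list score was treated as falling into 2 clusters where a mixture of 2 normal distributions (scikit-learn 1.9.0) improved the Bayesian information criterion by more than 10 and each cluster held at least 6 libraries. Correlations are then given within clusters.

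The lists, the score, the tests, the rule for named genes and most alternatives were fixed before the data were examined. The rule named the 10 genes with the smallest p in each direction for the T-cell score (adjusted p under 0.05, mean log2 CPM of at least 1, same sign in both name series), and the 8 genes with the largest log2 difference in each direction between name series. It further named the 10 genes with the largest standard deviation (both at mean log2 CPM of at least 3), up to 4 members of each list by p, and all checkpoint genes. Clone-named genes, pseudogenes, immunoglobulin and T-cell receptor segments and sex-specific genes were excluded from the rule.

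Alternatives covered DESeq2 1.42.0 (its size factors and its Wald test), limma-voom, other filters, other covariates, other scores, each name series alone and libraries left out. Alternatives chosen after seeing the data were a filter that treats all libraries as 1 group, removal of libraries with liver or lung transcripts, restriction to genes or score genes without a gene on the opposite strand, thinning to the smallest total, and removal of GC content and length trends.

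The median total count was 10.8 M per library, and the smallest 5.45 M. The tests were tried on simulated counts for 26428 genes with 200 changed genes. The changed genes were drawn only from genes above a minimum mean CPM, so recovery at low counts was not measured. The runs for the score and the interaction held no difference between name series. For the T-cell score, edgeR recovered 86% of the genes with a slope of 0.5 and 99% of those with a slope of 1. For the name series, it recovered 20% of the genes with a log2 difference of 0.5 and 78% at 1. For the interaction, it recovered 30% at 0.5 and 79% at 1. Of its calls, 3.14%, 4.85% and 6.03% were false in these 3 tests. P values take each biopsy as a replicate, since the labels give 1 biopsy per patient. All random draws used fixed seeds. None of the 1770 pairs of libraries held identical values, and the smallest chi-square per gene between any pair was 22.2, where sampling noise alone gives about 1.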

Results

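The series set out to find correlates of T-cell infiltration in tumours of patients with advanced cancer who received immunotherapy. RNA was profiled in 60 biopsies, each from a separate patient, which form a single labelled group. The total estimated count per library had a median of 10.8 M, with quartiles of 9.65 M and 19.2 M. The median was 24.1 M in the 22 YZ libraries and 9.86 M in the 38 YZHA libraries. A median of 37573.5 genes had a count above 0.

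**Figure D1:**
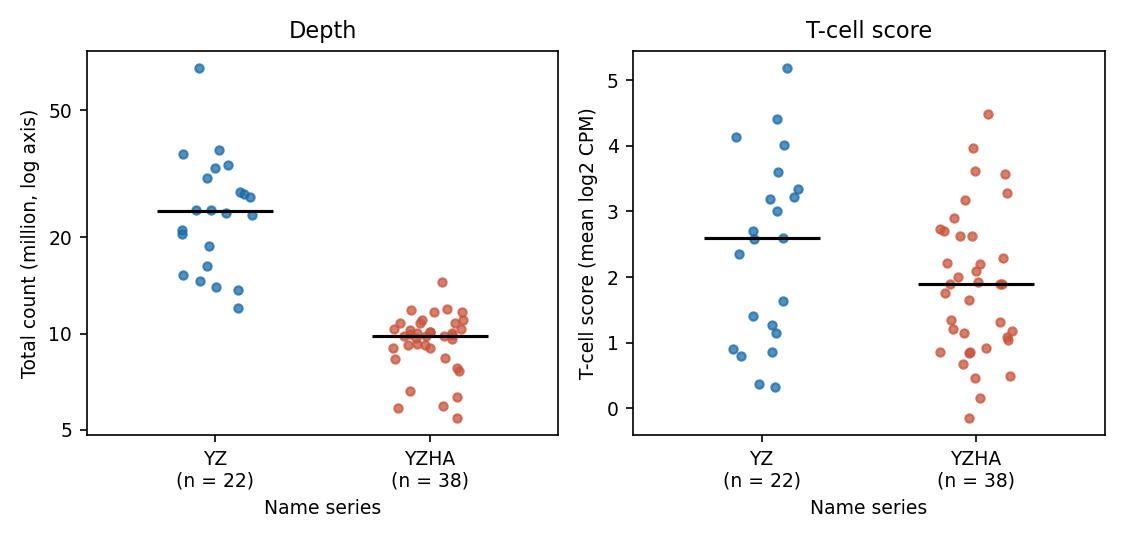
Total count (M) on a log axis (left) and T-cell score in mean log2 CPM (right) for each of the 60 libraries, split by name series; points are libraries and bars are medians. Median depth was 24.1 M in YZ and 9.86 M in YZHA, while the T-cell scores of both series overlapped.

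Melanocytic transcripts were present in most of the biopsies. MLANA, a melanocyte antigen, reached at least 10 CPM in 56 of 60 libraries, as did SOX10, a transcription factor of the neural crest lineage whose exons lie within an opposite-strand gene. TYR did so in 50 libraries, PMEL and DCT in 48 and S100B in 47. Keratin genes of the epidermis divided the samples, with KRT14 at 10 CPM or more in 26 libraries. The 10 expressed genes with the largest spread between libraries were KRT1, KRT5, LINC00273, FLG, DSC3, PKP1, TYRP1, FLG2, HRNR and DCT. Of these, 7 encode keratins, desmosomal or cornified-layer proteins, and TYRP1 and DCT encode enzymes of melanin synthesis. Part of this spread lies between the name series, with mean log2 CPM in YZ and YZHA of -1.56 and 6.74 for LINC00273 and -0.51 and 5.81 for HRNR. An opposite-strand gene overlaps 4 of the 10, against 48.2% of all tested genes outside the score. ALB, the main hepatocyte transcript, was at 1000 CPM or more in 3 libraries, and SFTPC, a surfactant gene of the lung, was at 100 CPM or more in 6. Together these made up 9 libraries.

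The T-cell score was spread continuously, with a mean of 2.07 ± 1.24 log2 CPM (SD, n = 60) and a range from -0.14 to 5.18. It was 2.41 ± 1.41 in YZ (SD, n = 22) and 1.87 ± 1.10 in YZHA (SD, n = 38). None of 5 technical measures was associated with it after adjustment. The largest correlation was with log2 total count (Pearson's r = 0.295, permutation p = 0.0223, adjusted p = 0.111; Spearman's rho = 0.288, permutation p = 0.0262, adjusted p = 0.131). Within the series this r was 0.190 in YZ and 0.266 in YZHA, and it was 0.299 without the 2 libraries farthest from the median score.

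Of the genes that rose with the T-cell score, T-cell receptor segments aside, the smallest p belonged to IKZF3, a lymphoid transcription factor (slope 0.92 ± 0.05, SE, n = 60; adjusted p = 1.72e-24, edgeR quasi-likelihood test; identifier ENSG00000161405, chromosome 17, 39757715 to 39864188). LINC00861, a long non-coding RNA, had a slope of 1.40 ± 0.08 (SE), and TRAF3IP3, a signalling adaptor, 0.95 ± 0.05. SLAMF6, IL2RG, INPP5D, IL21R, RAC2, CD96 and RCSD1 completed the 10 genes named by the rule, with slopes between 0.69 and 0.98. At the other end, SPRY2, a feedback inhibitor of receptor tyrosine kinase signalling, fell with a slope of -0.66 ± 0.11 (SE, n = 60; adjusted p = 7.82e-06; identifier ENSG00000136158, chromosome 13, 80335976 to 80340951).

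Of 26413 genes outside the score, 1657 rose and 673 fell with it, and 2296 of these 2330 genes had the same sign in both name series. Slopes of at least 0.5 in size were seen for 667 rising and 205 falling genes. The 10 falling genes with the smallest p under the naming rule were SPRY2, the proton pump subunit ATP6V1B1 (-0.62), the collagen COL20A1 (-2.07), TRIM45 (-0.37), the protocadherin PCDHGC4 (-0.48), LGI4 (-0.88), TRO (-0.59), the adhesion receptor ADGRA3 (-0.33), the tubulin acetyltransferase ATAT1 (-0.36) and RBFA (-0.23). With the pan-leukocyte score added, 6 of these 10 turned sign, namely SPRY2 (0.25), ATP6V1B1 (0.28), COL20A1 (0.023), LGI4 (0.081), TRO (0.31) and ATAT1 (0.10), none of them passing. In the published 18-gene list 15 of 17 measured genes rose, or 16 adjusted over the list alone. Immunoglobulin and T-cell receptor segments rose in 66 of 70 cases and none fell. Among protein-coding genes, 1225 rose and 437 fell. The counts of associated genes were 970 in YZ alone and 1155 in YZHA alone, and 595 when a pan-leukocyte score was added to the model. Of the 673 falling genes, 354 stayed called with limma-voom and 331 without the 2 libraries farthest from the median score. COL20A1, the steepest of the named falling genes, had a median of 1.06 CPM and a maximum of 2421 CPM.

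Effector genes of cytotoxic cells rose together. In the cytotoxic list 10 of 11 measured genes rose, also when adjusted over the list alone, led by PRF1 (1.04 ± 0.09, SE, n = 60), GZMA (1.19 ± 0.11), NKG7 (1.16 ± 0.11) and GZMK (1.07 ± 0.12). These genes encode the pore-forming protein, granzymes and a granule protein of killer lymphocytes. In the regulatory T-cell list 4 of 7 rose, among them FOXP3, the lineage factor (0.56 ± 0.09), and IL2RA (0.56 ± 0.08), and the count was the same adjusted over the list alone. Co-stimulatory genes rose in 8 of 10 cases, both over all genes and adjusted over the list alone, with ICOS at 1.25 ± 0.09, CD27 at 0.98 ± 0.10, CD80 at 0.78 ± 0.08 and TNFRSF9 at 0.49 ± 0.06. In the NK-cell list, KLRF1 (0.59 ± 0.11) and KLRD1 (0.24 ± 0.05) rose among 5 measured genes, with the same 2 adjusted over the list alone. With the pan-leukocyte score added, KLRF1 stood at -0.34.

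Inhibitory receptors and their ligands rose in step with T cells. Of 14 checkpoint and exhaustion genes 12 rose, and 13 did so adjusted over the list alone. The steepest were BTLA (1.26 ± 0.09, SE, n = 60), TIGIT (1.10 ± 0.08), IDO1, a tryptophan-degrading enzyme (1.02 ± 0.13), CTLA4 (0.91 ± 0.11) and LAG3 (0.90 ± 0.13). TOX (0.83), CD96 (0.76), PDCD1 (0.58), HAVCR2 (0.48), VSIR (0.48), ENTPD1 (0.40) and PDCD1LG2 (0.40) rose less steeply. Much of the exon length of VSIR (100%), ENTPD1 (96.9%), IDO1 (94.7%) and HAVCR2 (51.8%) lies within opposite-strand genes. Their counts in YZHA, and so their slopes, are uncertain. CD274, the gene of PD-L1, had a slope of 0.25 ± 0.10 (adjusted p = 0.115), and LAYN 0.23 ± 0.12 (adjusted p = 0.257). With the pan-leukocyte score added, ENTPD1 stood at -0.091.

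**Figure D2:**
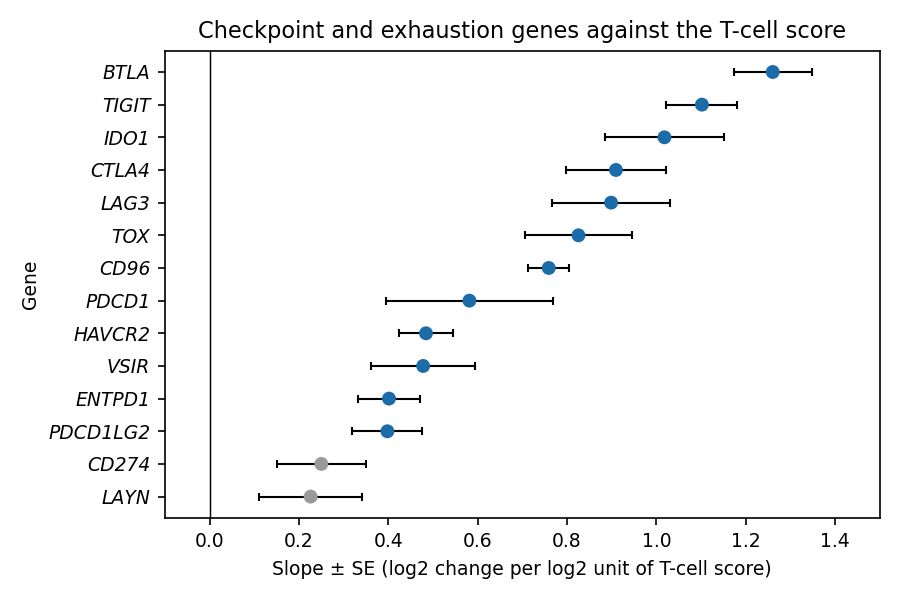
Slope of each checkpoint and exhaustion gene on the T-cell score, in log2 change per log2 unit of score, over 60 libraries; bars are SE, blue points passed an adjusted p of 0.05 and grey points did not. Of 14 genes 12 passed, from BTLA at 1.26 down to PDCD1LG2 at 0.40, while CD274 at 0.25 and LAYN at 0.23 did not. Counts of VSIR, ENTPD1, IDO1 and HAVCR2 in YZHA are uncertain, because most of their exon length lies within opposite-strand genes.

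Interferon-gamma response and antigen presentation genes rose without exception. All 16 interferon-gamma response genes rose, with IRF8 at 0.97 ± 0.07 (SE, n = 60), GBP5 at 1.15 ± 0.10, CIITA at 0.79 ± 0.07 and IRF1 at 0.76 ± 0.07. All 15 MHC class I presentation genes rose, with NLRC5, the class I transactivator, at 0.63 ± 0.05, HLA-F at 0.62 ± 0.08 and PSMB9, an immunoproteasome subunit, at 0.63 ± 0.08. All 13 class II genes rose, among them HLA-DPB1 (0.74 ± 0.07) and CD74 (0.76 ± 0.08). These counts were the same adjusted over the list alone. Of 16 type I interferon response genes only RSAD2 (0.62 ± 0.17) and OAS1 (0.42 ± 0.14) rose, or 4 adjusted over the list alone. RSAD2 stood at -0.14 with the pan-leukocyte score added. The type I list as a whole had adjusted p = 6.16e-05 in camera and adjusted p = 0.443 with an estimated correlation. HLA genes are highly similar to each other, so the division of their counts is uncertain.

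B-lineage and lymphoid-organ genes followed the score as well. In the B-cell list 11 of 12 genes rose, led by PAX5 (1.33 ± 0.13, SE, n = 60) and the receptor component CD79A (1.48 ± 0.15). In the plasma-cell list 9 of 10 rose, with CD38 at 0.92 ± 0.08 and MZB1 at 1.04 ± 0.15. Of 12 genes linked to tertiary lymphoid structures 9 rose, among them LTB (1.15 ± 0.11), CCR7 (1.14 ± 0.12) and CR2 (0.86 ± 0.10). Adjusted over the list alone, the counts of these 3 lists were unchanged. Chemokine genes rose in 8 of 12 cases and in 11 adjusted over the list alone, with CCL5 at 0.76 ± 0.07, CCL19 at 1.36 ± 0.17, CCL21 at 1.27 ± 0.18 and CXCL13 at 1.15 ± 0.18. The pan-leukocyte score, when added, moved PAX5 to -0.13 and CCL21 to -0.076.

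Myeloid lists were less uniform. In the macrophage list 11 of 16 genes rose and 13 did so adjusted over the list alone, with C1QB at 0.92 ± 0.12 (SE, n = 60), C1QC at 0.76 ± 0.10 and SIGLEC1 at 0.55 ± 0.07. In the list of type 1 conventional dendritic cells 5 of 9 rose, among them WDFY4 (0.88 ± 0.07) and FLT3 (0.95 ± 0.14). CADM1, an adhesion molecule also made by other cells, fell (-0.51 ± 0.15) and was picked out after its value was seen. Adjusted over the list alone, 7 rose and 1 fell. In the list of plasmacytoid dendritic cells 4 of 5 rose, both over all genes and adjusted over the list alone, including CLEC4C (0.65 ± 0.09) and LILRA4 (0.84 ± 0.14). CLEC4C stood at -0.13 with the pan-leukocyte score added. Of 11 neutrophil genes only MNDA rose (0.49 ± 0.15), also adjusted over the list alone. With the pan-leukocyte score added it fell instead (-1.33 ± 0.27, adjusted p = 0.00319). None of 8 mast-cell genes passed (KIT -0.31 ± 0.20). All 12 pan-leukocyte genes rose, among them CORO1A (0.99 ± 0.06) and PTPRC (0.97 ± 0.06).

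Tumour-lineage and stromal lists showed few calls. None of 14 melanocyte-lineage genes passed, with ERBB3 at -0.32 ± 0.11 (SE, n = 60; adjusted p = 0.0528) and SOX10 at -0.35 ± 0.14 (adjusted p = 0.115), and none of 10 genes of dedifferentiated melanoma did. None of 8 cancer testis antigens passed (MAGEC2 -0.97 ± 0.42). That list leaned down with adjusted p = 0.0124 in camera and adjusted p = 0.443 with an estimated correlation. In the fibroblast and matrix list MMP2 fell (-0.54 ± 0.18) among 16 genes, and none passed adjusted over the list alone. Endothelial genes PECAM1 (0.48 ± 0.10) and VWF (0.41 ± 0.14) rose among 13, with 9 rising adjusted over the list alone. With the pan-leukocyte score added, PECAM1 stood at -0.42, VWF at -0.054 and the r of the endothelial list score at -0.122, none of them passing. The endothelial list had adjusted p = 0.000442 in camera and adjusted p = 0.485 with an estimated correlation.

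Proliferation and signalling lists hardly moved. None of 17 cell-cycle genes passed (CCNB1 -0.31 ± 0.12, SE, n = 60), while the list leaned down with adjusted p = 2.11e-05 in camera and adjusted p = 0.443 with an estimated correlation. The 13 mitochondrially encoded genes behaved alike, with adjusted p = 0.000933 and adjusted p = 0.615 with an estimated correlation. Of 13 WNT and beta-catenin target genes TCF7, which is also a transcription factor of T cells, rose (0.70 ± 0.08), and SOX4 fell (-0.34 ± 0.11). Adjusted over the list alone, 2 rose and 1 fell. SOX4 stood at 0.058 with the pan-leukocyte score added. No gene passed in the lists of MYC targets, hypoxia, glycolysis, oxidative phosphorylation, TGF-beta response and mesenchymal transition. In the unfolded protein response list HERPUD1 (0.29 ± 0.06) and DNAJB9 (0.25 ± 0.08) were among 3 of 11 that rose, and 4 did adjusted over the list alone. DNAJB9 stood at -0.17 with the pan-leukocyte score added. HSPA1A (0.52 ± 0.15) and HSPA1B (0.48 ± 0.14) were the 2 of 11 heat-shock genes that rose, or 3 adjusted over the list alone. In YZ alone their slopes were -0.10 and -0.20. EXO1 fell (-0.39 ± 0.11) among 15 DNA repair genes, also adjusted over the list alone.

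Genes of the liver and lung also passed against the score. In the hepatocyte list 6 of 7 genes fell, or 7 adjusted over the list alone, with TTR at -1.77 ± 0.36 (SE, n = 60) and HP at -2.15 ± 0.47. All 3 measured lung alveolus genes rose, with SFTPB at 2.21 ± 0.65. Neither list passed as a whole, with adjusted p = 0.548 for hepatocyte and 0.331 for lung alveolus genes in camera with the preset correlation. The hepatocyte list score had r = -0.038 with the T-cell score (permutation p = 0.778, adjusted p = 0.830). Its rho was 0.240 (permutation p = 0.0653, adjusted p = 0.141), opposite in sign to the slopes. Without the 9 libraries that hold ALB or SFTPC transcripts, a choice made after seeing the data, 0 of the 6 and 0 of the 3 passed. The slopes were then -0.21 ± 0.13 for TTR, 0.15 ± 0.09 for HP and 0.05 ± 0.10 for SFTPB, which stood at -2.71 with the pan-leukocyte score added. SERPINA1, the hepatocyte gene that fell only when adjusted over the list alone (-1.13 ± 0.38), rose without those 9 libraries (0.56 ± 0.17, adjusted p = 0.0318, edgeR quasi-likelihood test). PIP fell (-1.16 ± 0.33) among 5 genes of sweat gland and hair follicle, TTN (0.80 ± 0.13) and TNNT1 (0.54 ± 0.18) rose among 6 of skeletal muscle, HBA2 (0.79 ± 0.25) rose among 6 of erythrocytes, and MUC1 (0.97 ± 0.33) rose among 12 of simple epithelium. Adjusted over the list alone, the counts of these 4 lists were 1, 3, 2 and 1. In YZHA alone TNNT1 stood at -0.064. None of 12 basal and 14 differentiated keratinocyte genes passed.

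In camera, 22 of 52 lists passed with the preset correlation and 17 held with an estimated correlation. Those that did not hold were type I interferon response, cancer testis antigen, endothelium, cell cycle and mitochondrially encoded genes. The median slope and the camera direction differed in sign for adipocyte, simple epithelium, brain tissue, TGF-beta response and heat-shock genes, none of which passed.

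List scores were correlated with the T-cell score over 52 lists. Of these 19 passed, all with a positive r and with the same sign within both name series. The checkpoint score had r = 0.955 (permutation p = 1e-05, adjusted p = 3.1e-05; rho = 0.964, permutation p = 1e-05, adjusted p = 3.1e-05), with 0.949 in YZ, 0.956 in YZHA and 0.960 without the 2 libraries farthest from the median score. The interferon-gamma score had r = 0.824 and rho = 0.851 at the same p values, with 0.834 in YZ, 0.806 in YZHA and 0.869 without those 2 libraries. The macrophage score had r = 0.544 and rho = 0.574 at the same p values, with 0.512, 0.522 and 0.665. A p of 1e-05 is the smallest these permutations can give. The type I interferon score had r = 0.331 (permutation p = 0.00917, adjusted p = 0.0251; rho = 0.433, permutation p = 0.0005, adjusted p = 0.00144), with 0.568 in YZ and 0.156 in YZHA, and 0.437 without those 2 libraries.

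The WNT and beta-catenin score had r = 0.016 (95% interval -0.239 to 0.269; permutation p = 0.903, adjusted p = 0.939; rho = 0.046, permutation p = 0.724, adjusted p = 0.819), with 0.067 in YZ, 0.051 in YZHA and 0.113 without the 2 farthest libraries. It includes TCF7, which is also a transcription factor of T cells (slope 0.70), and the r without TCF7 was not computed. The melanocyte-lineage score had r = -0.083 (permutation p = 0.529, adjusted p = 0.714; rho = -0.057, permutation p = 0.668, adjusted p = 0.789), with -0.071 in YZ, -0.104 in YZHA and 0.095 without those 2 libraries. The B-cell score fell into clusters of 9 and 51 libraries, within which r was 0.846 (exact permutation p = 0.00219) and 0.718 (permutation p = 1e-05).

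**Figure D3:**
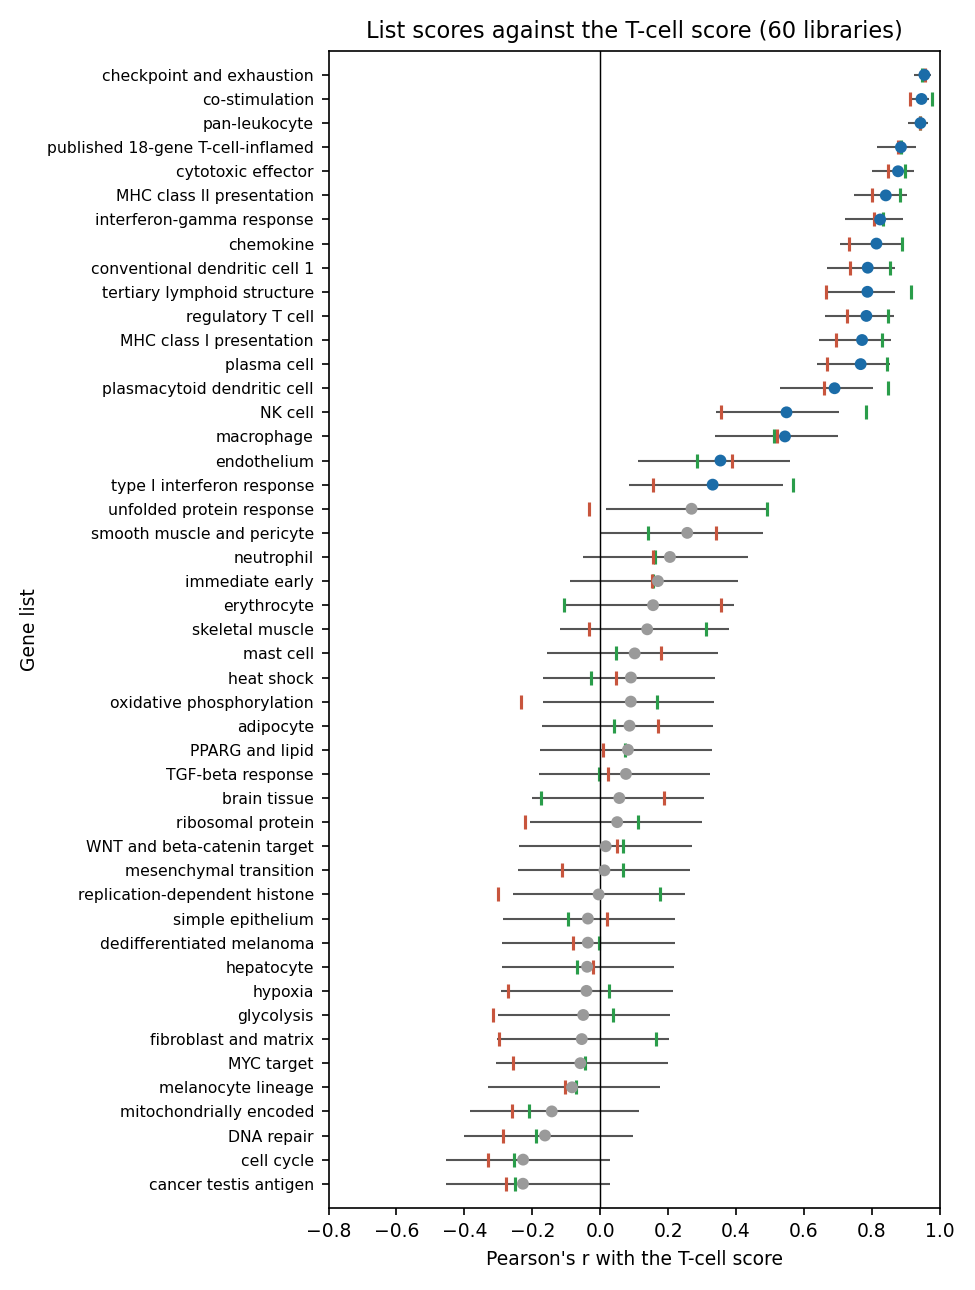
Pearson's r between each list score and the T-cell score over 60 libraries, for the lists that did not fall into clusters; lines are 95% intervals, blue points passed an adjusted p of 0.05, grey points did not, and ticks give r in YZ (green) and YZHA (red). The checkpoint score lies highest at 0.955, while the WNT and beta-catenin score lies at 0.016.

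The name series differed in the genes that lie opposite other genes. Non-coding genes lying inside a gene on the opposite strand were higher in YZHA by a median of 3.03 on the log2 scale (95% bootstrap interval 2.75 to 3.29, 2365 genes). Those inside a gene on the same strand had a median of -0.15 (interval -0.17 to -0.13, 1648 genes). Processed pseudogenes within an opposite-strand gene had a median of 6.53 (597 genes). These intervals are across genes, which are not independent replicates. Of the mitochondrial transfer RNA genes, MT-TC was higher by 5.81 ± 0.44 (SE, n = 22 and 38), whereas 12 of 13 mitochondrially encoded messenger RNAs were lower in YZHA, with MT-CO1 at -0.99 and MT-ND4 at -1.13. No annotated gene lies opposite MT-TC, but overlap was taken from annotated genes alone, so opposite-strand transcripts beyond them were not counted. Whether the strand of the reads bears on MT-TC was not tested.

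Between the name series 11823 of 26428 genes differed, 6087 of them higher and 5736 lower in YZHA. Of 16312 protein-coding genes, 4967 were lower and 1435 higher, and the rest did not pass. Of 7817 other non-coding genes 3595 were higher and 569 lower, and of 2229 pseudogenes 1057 were higher and 156 lower. Among the genes open to naming, which leave out pseudogenes, clone-named genes and those with a mean log2 CPM under 3, the largest differences upward were in LINC00273 (9.31 ± 0.65), MT-TC, SPDYE16 (5.70 ± 0.27), PLAC4 (5.43 ± 0.31), STARD13-AS (5.24 ± 0.27), PRR26 (4.27 ± 0.32), TFAP2A-AS2 (4.21 ± 0.48) and GSN-AS1 (4.03 ± 0.20). Of these 8, 6 overlap a gene on the opposite strand, so the origin of their counts is uncertain. Among all tested genes outside the score, 48.2% have such an overlap. So do 4 of the 8 genes that the rule named downward, IGF1 for 91.5% of its exon length, and its count in YZHA is uncertain too. Under the same limits, among the largest downward were those in ADD2 (-3.12 ± 0.47), RPS29 (-2.76 ± 0.18), the growth factor gene IGF1 (-2.65 ± 0.34), PCSK5 (-2.65 ± 0.70), MIR17HG (-2.44 ± 0.41), FCRLA (-2.39 ± 0.44) and RMRP (-2.38 ± 0.34), which the annotation lists under a further identifier. The mean log2 CPM in YZ and YZHA was 5.99 and 5.63 for PCSK5, 4.18 and 3.17 for ADD2, and 4.48 and 3.69 for MIR17HG, so their mean log2 levels lay closer than the fitted differences. PCSK5 stood at 0.26 when the mitochondrial and histone shares were added. The share of variance on the leading principal component was 26.6%, and that component had r = 0.987 with the name series.

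**Figure D4:**
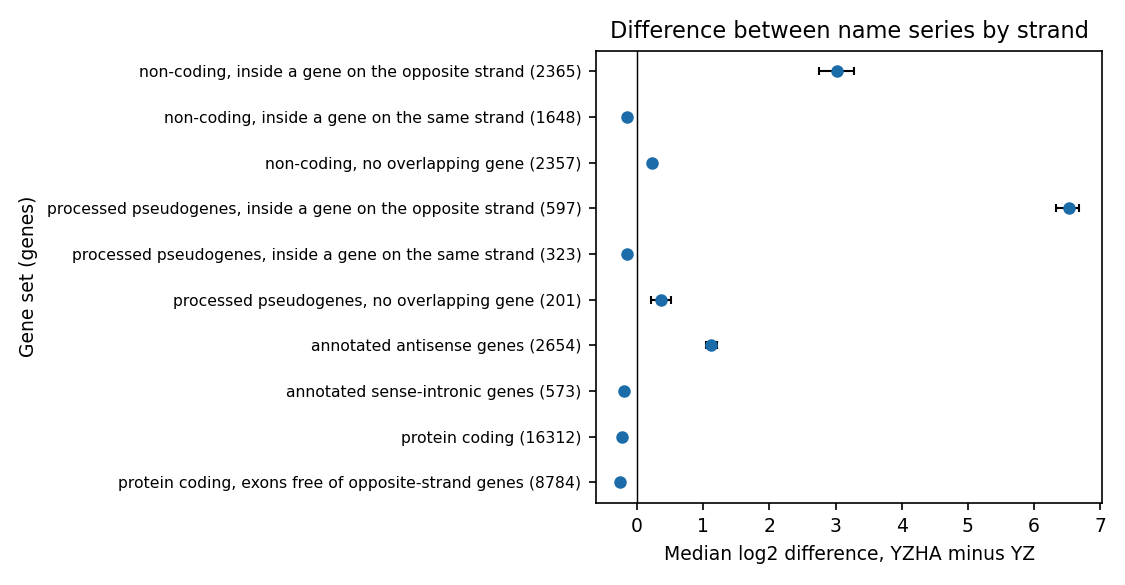
Median log2 difference between name series, YZHA minus YZ, for sets of genes defined by their position relative to other genes; bars are 95% bootstrap intervals and the number of genes is in brackets. Non-coding genes within an opposite-strand gene lie at 3.03 and those within a same-strand gene at -0.15.

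Genes of several housekeeping lists were lower in YZHA when tested singly. In camera 10 lists passed with the preset correlation and 0 with an estimated correlation, where each of these 10 had adjusted p = 0.984. The single genes given as examples here, and MT-CO1 and MT-ND4, were chosen after their values were seen. Of 15 oxidative phosphorylation genes 14 were lower (15 adjusted over the list alone), with ATP5MC3 at -1.68, and the list had adjusted p = 0.00014 in camera and adjusted p = 0.984 with an estimated correlation. Of 17 ribosomal protein genes 14 were lower (15 adjusted over the list alone), with RPLP1 at -0.98, and of 12 glycolysis genes 9 were lower (10 adjusted over the list alone), with GPI at -0.92. Of 11 unfolded protein response genes 8 were lower (8 adjusted over the list alone), with HERPUD1 at -0.84. Genes of immune lists were lower as well, with 11 of 16 interferon-gamma genes (13 adjusted over the list alone) and 9 of 16 macrophage genes (9 adjusted over the list alone). IDO1 was lower by -1.84, PSMB9 by -1.23 and HLA-DMB by -1.35. MYC target (9 of 16), histone (7 of 15) and MHC class II genes (7 of 13) were lower too, with the same counts adjusted over the list alone.

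Slopes on the T-cell score differed between the name series for 56 of 26413 genes, 23 with a higher and 33 with a lower slope in YZHA, by edgeR's interaction test. GPR18, a receptor of lymphocytes, had a slope of 1.43 ± 0.17 in YZ (SE, n = 22) and 0.23 ± 0.09 in YZHA (SE, n = 38), with adjusted p = 0.000243. CXCR6, a chemokine receptor, had 0.92 ± 0.14 and 0.21 ± 0.09. SIRPG-AS1, annotated antisense to the T-cell gene SIRPG, had 0.05 ± 0.18 and 1.16 ± 0.13. All 3 genes lie within an opposite-strand gene, and mean log2 CPM in YZ and YZHA was 0.087 and 3.63 for GPR18 and 1.70 and 3.50 for CXCR6. Their counts in YZHA are uncertain, because the strand setting of the counting is not known. These 3 genes were chosen after their values were seen. The same doubt holds for other genes named here that lie mostly within an opposite-strand gene. Among them are GZMK, CCL5, IRF1 and VSIR (100% of exon length each), ENTPD1 (96.9%), TTN (95.4%), IDO1 (94.7%) and CD27 (89.3%).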

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

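The tests of unspliced RNA and of overlap among the genes with differing slopes were chosen after the result was seen. Slopes on the T-cell score differed between the name series for 56 genes outside the score. Among the genes named here, the interaction (YZHA minus YZ) was -1.19 ± 0.18 for GPR18, -0.80 ± 0.15 for CD5, which is part of the score, -0.77 ± 0.15 for TBC1D10C, -0.78 ± 0.17 for CD37, -0.73 ± 0.17 for CLEC4C, -0.71 ± 0.16 for CXCR6 and 1.11 ± 0.22 for SIRPG-AS1 (SE, n = 22 and 38). Of 30 splits of the libraries into 22 and 38, the real one included, 3 gave as many genes, the highest of the others giving 76. The other splits were fitted without the name series in the model, so their counts are not a like-for-like comparison. Chance was not excluded for this count. Adjusted p ranged from 0.000243 for GPR18 to 0.0298 for CXCR6 and CLEC4C.

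Antisense and pseudogene counts were higher in YZHA, and it may be that the strand of the reads was not used when YZHA was counted. Non-coding genes inside an opposite-strand gene lay 3.18 above those inside a same-strand gene (log2, 95% bootstrap interval 2.90 to 3.45). The same-strand genes showed no rise (median -0.15). However, their mean level in YZ was already higher than that of the opposite-strand genes. The same added counts would raise them less on the log2 scale, so more unspliced RNA or DNA in YZHA stays open. Non-coding genes without an overlapping gene had a median of 0.23, with 890 of 2357 higher and 163 lower, and processed pseudogenes without one had 0.36, with 89 of 201 higher and 8 lower, which unused strand does not account for. Depth is argued against because 96.5% of the 4652 higher non-coding genes and pseudogenes were still called after thinning all libraries to 5447816 counts. Across 1417 antisense genes, the slope on the score followed that of the opposite-strand partner with rho = 0.533 in YZHA and 0.094 in YZ, a difference of 0.439 (interval 0.372 to 0.506, across genes, which are not independent).

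Genes with differing slopes overlapped an opposite-strand gene more often than tested genes (71.4% against 48.2%, odds ratio 2.69, Fisher's exact p = 0.000671), but CLEC4C has no such overlap. CD5 has none either, but as a score gene it was not among the genes of this test. CD37 (0.54, adjusted p = 0.20) and TBC1D10C (0.31, adjusted p = 0.502) did not pass as higher in YZHA in edgeR's test. Yet their mean log2 CPM was 3.40 in YZ and 4.40 in YZHA for CD37 and 2.57 and 3.53 for TBC1D10C. GPR18 (2.64, adjusted p = 1.22e-07), CXCR6 (1.36, adjusted p = 3.65e-05) and SIRPG-AS1 (3.89, adjusted p = 4.51e-11), which lie within an opposite-strand gene, were higher in YZHA. The cause of the differing slopes stays open.

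For the other counts, 1 of 30 splits into 22 and 38 libraries gave as many differing genes as the real 11823, the real one itself, and the highest other gave 215. For the association with the T-cell score, 1 of 30 orders of the score within series gave as many genes as the real 2330, the real order itself, and the highest other gave 184. Neither count was reached by any other split or order.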

How the results depend on the processing

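The alternatives with the 1-group filter, without opposite-strand overlap, without liver and lung libraries, or with GC and length trends removed were chosen after seeing the data. The T-cell score count (2330) stayed within 1.5 times under 13 of 20 alternatives, and was 5011 without a filter, 595 with the pan-leukocyte score, 1500 with the 18-gene score, 1283 with GZMA and PRF1, 970 in YZ alone, 1155 in YZHA alone and 1481 among genes without opposite-strand overlap, where fewer samples or genes enter the last 3. In some settings the falling genes held less well than the rising ones. With limma-voom 354 of 673 falling and 1482 of 1657 rising genes stayed called, and without the 2 farthest libraries 331 and 1196. YZ alone kept 92 and 787, and YZHA alone 146 and 841. With DESeq2 size factors 669 and 1579 stayed. The series count (11823) was 25360 without a filter, 6925 at mean log2 CPM of at least 1, 6967 with the 1-group filter and 4148 among genes without opposite-strand overlap. Removing GC and length trends moved the share higher in YZHA from 51.5% to 32.5% and the median of all genes from -0.077 to -0.28. The interaction count (56) was 19 with limma-voom, 8 at mean log2 CPM of at least 1, 31 without the liver and lung libraries and 9 among genes without opposite-strand overlap. Passing list scores (19) became 10 given series and pan-leukocyte score, and passing lists between series fell from 10 to 0 with an estimated correlation. The cause was not tested. Adding the pan-leukocyte score, which tracks the T-cell score, kept 109 of 1657 rising and 18 of 673 falling genes called. The sign was kept by 1032 of the rising and 437 of the falling genes. Among genes checked singly and list scores that passed with or without the pan-leukocyte score, adding it turned the sign of ATAT1 (0.10), ATP6V1B1 (0.28), CCL21 (-0.076), CLEC4C (-0.13), COL20A1 (0.023), DNAJB9 (-0.17), ENTPD1 (-0.091), KLRF1 (-0.34), LGI4 (0.081), MNDA (-1.33), NAPSA (-0.082), PAX5 (-0.13), PECAM1 (-0.42), RSAD2 (-0.14), SFTPB (-2.71), SOX4 (0.058), SPRY2 (0.25), TRO (0.31) and VWF (-0.054), and of the list scores of plasmacytoid dendritic cells (-0.011), neutrophils (-0.378), endothelium (-0.122), TGF-beta response (-0.341) and mesenchymal transition (-0.370). Other list scores that passed in neither setting also turned sign. Among the genes checked singly, HSPA1A (-0.10) and HSPA1B (-0.20) turned in YZ alone, TNNT1 (-0.064) in YZHA alone, HP (0.15) and APOA2 (0.19) without the liver and lung libraries, and PCSK5 (0.26) with mitochondrial and histone shares. Of the hepatocyte list, CYP3A4 (0.12), TF (0.069) and SERPINA1 (0.56) also turned without the liver and lung libraries. No paired analysis was possible because the labels give a single group. Of simulated log2 differences of 0.5 between series, 20% were recovered.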

Other observations

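The test of liver tissue on hepatocyte list genes was chosen after the result was seen. Given the name series and the pan-leukocyte score, 10 list scores passed, 7 of them with a positive r. The largest were the checkpoint list (r = 0.726), the 18-gene list (0.685), the cytotoxic list (0.685), co-stimulation (0.620) and interferon-gamma response (0.571). Other lists hold 14 of the 17 measured genes of the 18-gene list, 7 of 16 interferon-gamma and 6 of 14 checkpoint genes. These lists are therefore not independent. Regulatory T cells (0.422) and MHC class I presentation (0.406) followed. Neutrophil (-0.378), mesenchymal transition (-0.370) and TGF-beta response (-0.341) scores passed with a negative r, and these 3 had not passed without that adjustment. B-cell (0.124), macrophage (0.094) and tertiary lymphoid structure (0.013) scores did not pass in that setting.

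The scores of 5 lists fell into 2 clusters. The differentiated keratinocyte score fell into clusters of 27 and 33 libraries with means of 5.93 and -0.71 log2 CPM. The basal score fell into clusters of 33 and 27 with means of 5.47 and 0.32. Within these clusters, r with the T-cell score was -0.070 and 0.036 for the differentiated score (permutation p = 0.729 and 0.842) and -0.139 and 0.269 for the basal score (permutation p = 0.442 and 0.175). The lung alveolus score fell into clusters of 6 and 54 libraries with means of 7.69 and 1.39, and r was 0.905 (exact permutation p = 0.0222) and 0.057 (permutation p = 0.680). The sweat gland and hair follicle score fell into clusters of 18 and 42, with r of -0.092 and -0.142 (permutation p = 0.718 and 0.367). None of these p values is adjusted.

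Genes that fell with the T-cell score may reflect fewer melanocytic cells or liver tissue in a few libraries. With the melanocyte-lineage score added, 544 of the 673 falling genes were still called and their median slope moved from -0.36 to -0.35. The melanocyte-lineage score itself hardly followed the T-cell score (r = -0.083), so adding it could move these slopes little. How well it tracks the share of melanocytic cells was not tested, so dilution of these cells stays open. Without the libraries with ALB or SFTPC, 377 were still called and 656 kept their sign, which argues against liver tissue as the whole cause. For the hepatocyte list itself, 0 of 6 falling genes were still called without those libraries and the median slope moved from -1.66 to 0.09. Those libraries were chosen by a hepatocyte transcript, so this loss follows from the choice and gives no evidence on the cause, which stays open. Dilution by leukocytes of other kinds stays open, since the pan-leukocyte score and the T-cell score were closely related (r = 0.943).

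The fall of SPRY2 led to the hypothesis that RAS-MAPK transcriptional output is lower in T-cell-rich biopsies. The score of 9 other output genes, among them SPRY4, DUSP6 and ETV5, had r = -0.274 with the T-cell score given the series (95% interval -0.496 to -0.020, permutation p = 0.0344). Without regard to series, Spearman's rho was -0.157 (permutation p = 0.230). None of the 9 genes passed on its own, although 8 had negative slopes, and the r without the 2 libraries farthest from the median score was -0.073. The slope of SPRY2 itself was 0.25 ± 0.29 (SE) with the pan-leukocyte score added. The interval reaches below and above the bound of -0.3 set in advance, so the hypothesis can be neither held nor excluded from these data.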
